A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

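The series measured gene expression in Saccharomyces cerevisiae, budding yeast, with 2-colour DNA microarrays. The strain was a BY4741 derivative labelled WSC1extMID2cyt. This label names WSC1 and MID2, genes of plasma membrane sensors of the cell wall integrity pathway. All 3 arrays used this strain, so nothing here compares it with BY4741 itself. A culture growing in rich medium at 24 °C was split, per the labels: one part stayed untreated and the other received 15 ng/ml caspofungin, and both were harvested after 2 hours. Caspofungin is an echinocandin that inhibits the synthase of the cell wall polymer beta-1,3-glucan. Each array carried RNA of both parts, labelled with Cy3 and Cy5. The 3 arrays analysed here are numbered 1, 2 and 4 in the labels. Treated RNA was in Cy3 on array 1 and in Cy5 on arrays 2 and 4.

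The deposited values are log2 ratios, 1 per row and array, as the authors prepared them. The base of the logarithm, the centring, the filter on spots and the direction of the ratio are not given in the sources used here, nor are the scanner and the normalization. Base 2 was assumed, so every fold stated rests on that assumption. Array 1, with swapped dyes, would have been turned had it correlated below 0 with both other arrays. It did not (r = 0.50 with array 2 and 0.05 with array 4), so the columns were taken as already turned to one direction. The second of these values is close to 0 and settles little. That direction remains open, so values are described as lying on the positive or the negative side. Signal intensities were not used here, so the precision is limited by the number of arrays and a spot's brightness is unknown.

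The table has 6209 rows. Of these, 5654 were matched to a gene by locus tag and 57 by synonym in the RefSeq gene table of assembly R64, and 498 kept the name in the file. Rows of one gene were averaged, which gave 6174 genes, and 1 gene among those tested came from more than 1 row. Coordinates are not printed because the build behind the array is not stated. Probe sequences were not used here, so members of near-identical families (Ty retrotransposon, FLO, PIR, IMD, histone and ribosomal protein genes) may share signal. A value was present for 40.6% of rows on array 1, 31.0% on array 2 and 11.9% on array 4. The tests used the 585 genes with a value on all 3 arrays.

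The series text describes 2 cultures, each hybridised with both dye orientations, which makes 4 arrays. Arrays 2 and 4 share an orientation and so came from different cultures under that design. Array 1 then shared its culture with one of them, and the labels do not say which. Arrays of one culture are technical replicates. Each gene's log2 ratio was therefore tested against 0 with limma (version 3.58.1, R 4.3.3, lmFit and eBayes) in 2 fits: with array 1 averaged with array 2, and with array 1 averaged with array 4. The larger of both p-values was kept and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Each fit had 1 residual degree of freedom per gene, plus a prior of 4.96 or 2.7 degrees of freedom. Sizes are the mean log2 ratio ± SD over arrays. The SD covers technical and biological spread together. For genes with values on arrays 1 and 2 alone it may hold technical spread only, because these arrays may share a culture.

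Before the data were examined, 26 gene lists were fixed, and the 13 with at least 3 tested members were compared with all other genes by limma's camera (two-sided, preset correlation 0.01, larger p of both pairings, Benjamini-Hochberg over lists). Camera with an estimated correlation and fry, which tests whether a list's genes move one way without comparing them with other genes, were alternatives. Lists over genes with values on at least 2 arrays were tested by cameraPR with the same preset correlation. This form of camera starts from each gene's moderated t-statistic. Those statistics came from 2 or 3 arrays and were not put on one scale. Genes named in the text were also chosen by a rule fixed then: 10 per side, by adjusted p and size where genes passed and otherwise by the largest smallest-array ratio of one sign; up to 4 members of each list past the threshold and of the first 5 lists; and WSC1 (SLG1 in the reference), MID2, FKS1, GSC2 and SLT2. Members with values on only 2 arrays were named after their values were seen. For each array alone, a list's median was placed among 10000 random lists of the same size, not matched on signal.

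On simulated data for this comparison (585 genes, 20 simulations, spread taken from the arrays, 30 genes changed at each size), the test recovered 10.3% of 4-fold changes and 0.167% of 2-fold changes, with 0.1 false calls per simulation. Counting the 3 arrays as separate replicates recovered 85.5% of 4-fold changes but made 10.5 false calls per simulation. All rates of this paragraph depend on how the simulated spread was split between cultures and arrays. That split was assumed, because the labels do not say which arrays share a culture. The rates are therefore not measured error rates or power for these arrays. A list of 8 genes shifted by 2-fold was called in 20 of 20 simulations by camera with the preset correlation, in 0 with an estimated correlation and in 11 by fry. Here a list counted as called at an unadjusted p under 0.05, and genes were drawn independently of one another. The alternatives were each pairing alone, 3 separate replicates without and with a dye term, centring, scaling, genes measured on at least 2 arrays, robust moderation, a test without moderation, other fold thresholds and leaving out each array.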

Results

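Transcript levels were compared between WSC1extMID2cyt yeast exposed to caspofungin for 2 hours and the untreated part of the same culture on 3 two-colour arrays. Array 1 gave 2520 ratios, array 2 gave 1924 and array 4 gave 741. The 3 arrays shared 585 genes, a further 1314 genes had a value on 2 arrays, and 3473 genes had none. Of the genes with a value on 2 arrays, 1278 were measured on arrays 1 and 2. Over the 585 shared genes Pearson's r across genes was 0.50 between arrays 1 and 2, 0.53 between arrays 2 and 4, and 0.05 between arrays 1 and 4. Genes are not independent replicates. The median log2 ratio of the shared genes was -0.14 on array 1, -0.14 on array 2 and 0.09 on array 4. All values below are log2 ratios with the sign as deposited, and whether positive means higher with caspofungin or lower is not stated. If the sign were turned, every side named here would be exchanged.

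The first question was which single genes differed between treated and untreated cells. On the positive side the carbonic anhydrase gene NCE103 (YNL036W) had the largest ratio that repeated on every array, at 2.72 ± 0.37 (SD, n = 3 arrays, as for the other genes of this paragraph). The cell wall protein gene NCW2 (YLR194C) averaged 1.88 ± 0.10, the second largest by its lowest array. TFS1, which encodes an inhibitor of carboxypeptidase Y, averaged 1.78 ± 0.44, the plasma membrane protein gene PUN1 1.52 ± 0.31, and SKI2, the gene of an RNA helicase, 1.91 ± 0.88. The wall mannoprotein genes SED1 and CWP1 averaged 1.17 ± 0.10 and 1.67 ± 0.89. The glutathione transferase gene GTT1 averaged 1.16 ± 0.34, and the open reading frames YOL150C and YNL208W averaged 1.32 ± 0.23 and 0.98 ± 0.26. On the negative side were 2 genes of adenine nucleotide synthesis, ADE13 at -1.33 ± 0.61 and ADE12 at -1.14 ± 0.42, and the glycine cleavage gene GCV3 at -1.18 ± 0.36. The transporter gene ATO3 averaged -1.18 ± 0.25 and MYG1 -1.15 ± 0.20. The genes UTP11, NIP7 (ribosome assembly) and RPL23B (a ribosomal protein) averaged -0.97 ± 0.20, -0.80 ± 0.29 and -0.89 ± 0.39. MGE1, a nucleotide exchange factor of mitochondrial Hsp70, averaged -0.70 ± 0.18 and the GTP-binding protein gene RBG1 -0.69 ± 0.08.

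None of these genes passed the test. The limma test over both culture pairings called 0 of 585 genes, and the smallest adjusted p was 0.078, for NCE103. At an unadjusted p under 0.05 there were 67 genes, 28 on the positive and 39 on the negative side. A one-sample test without moderation over the 3 arrays also called 0. The same sign was found on all 3 arrays for 276 genes (47.2%), where 3 independent arrays with even signs would give 25%. Arrays 1 and 2 shared the sign at 71.5% of genes, arrays 1 and 4 at 53.5% and arrays 2 and 4 at 69.4%. Had the remaining array been independent of the pair, 33.5%, 27.8% and 35.4% of genes would have had one sign on all arrays. Genes are not independent, and arrays 2 and 4 also share their dye orientation. At least 2-fold on every array was reached by 7 genes on the positive side (NCE103, NCW2, TFS1, PUN1, SKI2, YOL150C and SED1) and by 0 on the negative side. This balance depended on the setting: there were 9 positive and 17 negative genes without array 1, 9 and 2 without array 2, 44 and 14 without array 4, and 15 and 8 at 1.5-fold. The count of calls depended on the arrays used: it was 17 without array 1 (6 positive, 11 negative), 0 without array 2, and 209 without array 4 (89 positive, 120 negative), where the remaining arrays may both come from one culture. Without array 1, both remaining arrays held the treated RNA in Cy5. The calls and 2-fold counts there cannot separate treatment from a dye effect. With every array as a separate replicate and genes measured on at least 2 arrays, 48 of 1899 genes passed, 34 on the positive and 14 on the negative side. Of these, 18 had values on all 3 arrays, of which 2 share a culture under the design described. The other 30 had values on 2 arrays, which may share one. Where arrays share a culture, these p-values are too small.

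The second question was whether genes of the cell wall integrity pathway's response, known to be transcribed through the MAP kinase Slt2 and the factor Rlm1 under wall stress, moved as a group. They stood apart on the positive side. Of 24 listed genes, 8 were measured on all arrays, with a median log2 ratio of 0.97, and 7 of these 8 were positive on every array. The list differed from all other genes by camera (adjusted p = 5.33e-06). With an estimated correlation the call was lost (adjusted p = 0.828), as it was by fry (adjusted p = 0.446). NCW2, CWP1, PUN1 and SED1 led the list. PIR1 averaged 0.39 ± 0.71 and was near 0 on arrays 1 and 2. No member passed over all genes, and 5 of the 8 passed when adjusted over the list alone. Among 14 members with a value on at least 2 arrays the mean was positive for all 14. They included CRH1, a chitin transglycosylase gene, at 1.13 ± 0.30, the yapsin gene YPS3 at 1.16 ± 0.27, PRM5 at 1.09 ± 0.18 and SLT2 itself at 0.59 ± 0.24 (n = 2 arrays each). SPI1 had a value on array 4 alone, of -2.69. On single arrays the list's median was 0.95 on array 1 (15 genes), 0.87 on array 2 (14 genes) and 1.14 on array 4 (10 genes), each above the middle 95% of random lists. After turning the sign of any 1 array no list passed. That loss was largely fixed in advance, because the list lay on one side of every array and its values then cancel.

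**Figure D1:**
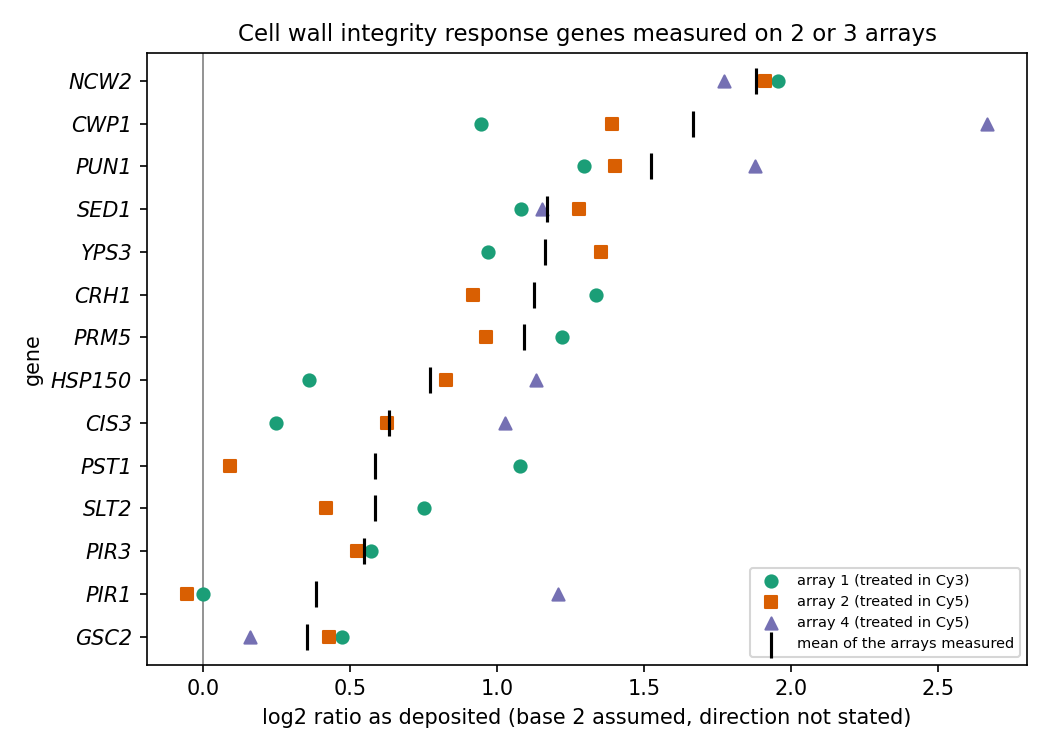
Log2 ratio as deposited (horizontal axis, base 2 assumed) of the 14 cell wall integrity response genes (vertical axis) measured on 2 or 3 arrays. Each symbol is 1 array and the black bar is the mean of the arrays measured; all 14 means lie above 0, from 0.35 for GSC2 to 1.88 for NCW2.

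Cell wall mannoproteins also lay on the positive side (median 0.52 over 9 genes, camera adjusted p = 0.032; adjusted p = 0.828 with an estimated correlation). Of the 9 genes, 5 were positive and 1 was negative on every array, and 3 passed when adjusted over the list alone. CWP1, SED1 and HSP150 (0.77 ± 0.39) were positive, and the flocculin gene FLO9 averaged -1.21 ± 0.87. The call rested on 5 members shared with the integrity response list: the other 4 had a median of -0.10 (adjusted p = 0.958). Scaling the arrays to one spread also ended it (adjusted p = 0.061). Of the sensor and kinase genes of the pathway, only RHO1, the GTPase that activates protein kinase C, was measured on all arrays, at 0.21 ± 0.24. WSC1 (SLG1) had 0.17 on array 1 and -0.27 on array 2, and MID2 had no value. The strain's label names both genes, so whether the WSC1 values come from the native gene is unknown. Over the 7 pathway genes with at least 2 values the median was -0.05, while the list's test pointed to the positive side (adjusted p = 0.453).

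The drug's target was covered thinly. FKS1, the main catalytic subunit of beta-1,3-glucan synthase, had no value, and GSC2, the alternative subunit, averaged 0.35 ± 0.17 (n = 3 arrays, limma adjusted p = 0.669). Among 12 genes of beta-glucan synthesis and remodelling with at least 2 values, 5 were positive and 2 negative on all their arrays, with a median of 0.21 (adjusted p = 0.064, and 0.040 without array 4). If arrays 1 and 2 share a culture, both p-values are too small. CRH1 and GSC2 are also on the integrity response list, and the beta-glucan list was not tested without them. CRR1, a homologue of CRH1, was highest at 1.86 ± 0.16 and the glucanase gene SCW11 lowest at -1.28 ± 0.30 (n = 2 arrays each). Of 5 chitin genes with at least 2 values, none was measured on array 4, and their median was 0.24 (adjusted p = 0.648).

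Cytosolic ribosomal protein genes lay slightly on the negative side. Their median was -0.22 over 76 genes, 35 of them negative and 0 positive on every array (camera adjusted p = 0.032; adjusted p = 0.828 with an estimated correlation). No member passed, over all genes or adjusted over the list alone. RPL23B averaged -0.89 ± 0.39, RPS24B -0.73 ± 0.51, RPS21B -0.63 ± 0.50 and RPL19B -0.59 ± 0.35. Centring each array on its own median brought the list's median to -0.16. On each array alone the list's median lay within the middle 95% of random lists. Without array 1 the list did not pass (adjusted p = 0.068). The 9 ribosome biogenesis genes tested did not pass (median -0.41, adjusted p = 0.504), with 5 negative and 1 positive on every array. Their median was -0.20 without array 2. With genes on 2 or more arrays the list passed (cameraPR adjusted p = 0.00046), as it did without array 4 (camera adjusted p = 0.00012). Over the 9 genes the adjusted p was 0.828 with an estimated correlation and 0.483 by fry, which were not run on the larger sets. In the former set 37 of 42 genes were negative on all arrays measured, with a median of -0.58, mostly from arrays 1 and 2. If these share a culture, this p is too small. Their median lay below 0 more clearly on array 2 (-0.86) than on array 1 (-0.32) or array 4 (-0.05), of which array 4 measured 9 genes. It lay below the middle 95% of random lists on array 2 alone, and within it on arrays 1 and 4. The difference between arrays was not tested.

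General stress response genes were measured on all arrays for 3 members, which had a median of 0.62 (adjusted p = 0.061), and 1 of them, TFS1, passed when adjusted over the list alone. Among 14 members with at least 2 values, 10 were positive and 0 negative on all their arrays, with a median of 0.69. The glycogen synthase gene GSY2 averaged 1.98 ± 0.05, the small heat shock protein gene HSP42 1.40 ± 0.12, PNC1 1.05 ± 0.04 and the disaggregase gene HSP104 0.66 ± 0.07 (n = 2 arrays each). On array 1 alone HSP12 had 1.76 and GAD1 -2.21. The list's adjusted p was 0.828 with an estimated correlation and 0.483 by fry. It was 0.061 with arrays 1 and 4 averaged, 0.054 after centring, 0.068 after scaling and 0.064 without array 1. The list passed with arrays 1 and 2 averaged (adjusted p = 0.033), with 3 separate replicates (0.042, and 0.040 with a dye term), without array 2 (0.025), without array 4 (5.94e-08) and with genes on at least 2 arrays (1.51e-08). All of these fits but the first count each array separately. Where 2 of those arrays share a culture, the p-value is too small.

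**Figure D2:**
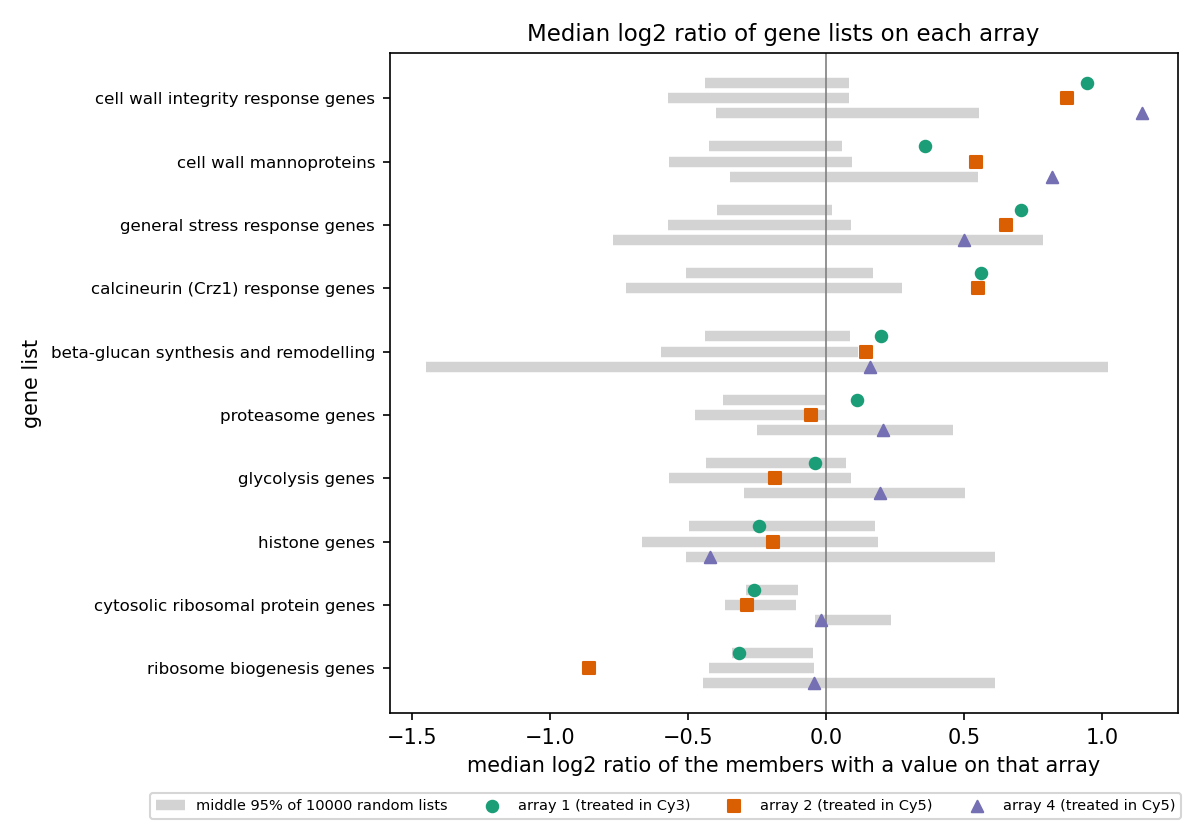
Median log2 ratio (horizontal axis) of 10 gene lists (vertical axis) on each array, over the members with a value there; grey bars span the middle 95% of 10000 random lists of the same size. The cell wall integrity response list lies beyond its bar on all 3 arrays, at 0.95, 0.87 and 1.14. So does the mannoprotein list, which shares members with it, at 0.36, 0.54 and 0.82. The general stress, calcineurin and beta-glucan lists lie above their bars on arrays 1 and 2.

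The other tested lists did not pass. Their medians were -0.38 for 7 histone genes (5 negative on every array, adjusted p = 0.176), 0.11 for 13 proteasome genes (adjusted p = 0.176), 0.25 for 5 drug efflux and oxidative defence genes (adjusted p = 0.230) and -0.20 for 5 amino acid synthesis genes (adjusted p = 0.865). Medians of the ergosterol (8 genes, 0.09), unfolded protein response (3 genes, -0.09), respiratory chain (6 genes, -0.04) and glycolysis (10 genes, -0.06) lists had an adjusted p of 0.958 each, and each of these 4 medians changed side under at least 1 alternative. For the unfolded protein response and respiratory chain lists the test pointed to the positive side. Lists with fewer than 3 shared genes were tested only over genes with at least 2 values, mostly from arrays 1 and 2. If these share a culture, the p-values are too small. An estimated correlation was not run there. Calcineurin response genes passed with a median of 0.62 (6 genes, adjusted p = 0.0090), led by the yapsin gene YPS1 at 1.25 ± 0.24 (n = 2 arrays), while PMR1 averaged -0.47 ± 0.19. CRZ1 had 1.16 on array 1 and -0.34 on array 2. The other members are shared: GSC2 with the integrity response list, YPS1 with mannoproteins, ENA1 with osmotic stress and PHO89 with phosphate response. The calcineurin list was not tested without them. Methionine and sulphate genes passed with a median of 0.95 (5 genes, adjusted p = 0.0023), which was 0.52 without array 4 and 1.21 without array 2. MET14 averaged 1.38 ± 0.46 and MET6 1.04 ± 0.17 (n = 2 arrays each), SAM1 averaged -0.14 ± 0.35 (n = 3 arrays), and on single arrays SUL2 had -1.52 and MET16 -0.64. The 5 cell separation genes were negative on all arrays measured, with a median of -0.60, but did not pass (adjusted p = 0.064). Osmotic stress genes had a median of 0.36 (6 genes, adjusted p = 0.069, and 0.043 without array 4). The remaining lists did not pass. Medians were -0.27 for 6 mating pheromone genes, 0.00050 for 6 G1/S genes, -0.24 for 3 G2/M genes, -0.18 for 11 phosphate response genes (whose test pointed to the positive side) and -0.20 for 12 iron regulon genes. Markers of MAT alpha cells, which a MATa culture should lack, had no value on any array. As 3473 of 6174 genes had none, this cannot bear on the cell type.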

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

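The fit over genes on at least 2 arrays for lists, and the mannoprotein list without shared members, were chosen after seeing the data. The count of single genes past the threshold stayed at 0 under each pairing alone, centring, scaling, robust moderation, no moderation and an added 2-fold minimum. It was 2 (NCE103 and NCW2) when the 3 arrays counted as separate replicates, and the same 2 genes passed with a dye term. The count was 48 with genes on at least 2 arrays, and ranged from 0 to 209 when 1 array was left out. The count of lists past the threshold, 3 of 13, was 0 with an estimated correlation, 0 with fry, and 6 of 25 with genes on at least 2 arrays, not including ribosomal proteins. It ranged from 2 to 9 when 1 array was left out: 2 of 13 without array 1, 5 of 14 without array 2 and 9 of 25 without array 4. In simulations with an assumed split of spread between cultures and arrays, an estimated correlation called a shifted list of 8 genes in 0 of 20. Under that assumption its failure for a list of that size carries little information. Fry called that list in 11 of 20. Lists of other sizes were not simulated. The simulated genes were independent, so whether the preset correlation makes false calls for correlated genes was not tested. The cell wall integrity response median was 0.97 with an estimated correlation (adjusted p = 0.828) and with fry (adjusted p = 0.446), passed under all other settings, and ranged from 0.84 to 1.10 with 1 array left out. The mannoprotein median was 0.57 and no longer past the threshold after scaling, 0.52 with an estimated correlation or fry, and -0.10, on the other side, without shared members; leaving out 1 array gave 0.55 to 0.68. The ribosomal protein median was -0.22 with an estimated correlation or fry and -0.24 with genes on at least 2 arrays (adjusted p = 0.067), none past the threshold, and -0.31 to -0.16 with 1 array left out. The count of genes at 2-fold on every array was 23 at 1.5-fold and 2 at 3-fold, and 11 to 58 with 1 array left out, where fewer arrays must agree and more genes have values. The 27 genes named by the fixed rule and measured on all 3 arrays kept their sign in 270 of 270 alternatives, 48 of them past the threshold. Each of the 27 has one sign on all 3 arrays, so averaging or leaving out arrays could not turn it. The kept signs therefore say little about robustness. Genes named otherwise, such as PIR1 and SAM1, whose arrays differ in sign, were not included. Lists that did not pass stayed so in 112 of 120 alternatives, and 10 medians near 0 (ergosterol, unfolded protein response, respiratory chain, glycolysis) changed side. Beyond the fewer or more genes and arrays each setting uses, the cause was not tested. No paired analysis was possible because each array is already a ratio within 1 split culture and there is 1 group.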

Other observations

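All tests in this part were chosen after the result was seen, except that on the purine and one-carbon genes, whose prediction was written before those members' values were looked at. Genes of purine and one-carbon metabolism were frequent on the negative side of arrays 1 and 2. ADE17 averaged -2.72 ± 0.34, MTD1 -2.37 ± 0.73, ADE1 -2.18 ± 0.46, ADE4 -1.91 ± 0.75 and SHM2 -1.87 ± 1.00 (n = 2 arrays each), beside ADE12, ADE13 and GCV3 above. A candidate explanation is that the genes of purine and one-carbon metabolism move together. It was tested on 12 further members, of which 10 had a value on at least 2 arrays. Their median was -0.82, 7 were negative and 1 (MIS1, 0.75 ± 0.52) was positive on both arrays, and 1e-04 of random lists had a median as low, the smallest share that 10000 lists can give. ADE2 averaged -0.96 ± 0.82, ADE8 -0.93 ± 0.29, GUA1 -0.83 ± 0.05, IMD3 -0.97 ± 0.45 and IMD4 -0.95 ± 0.30. None of the 10 was measured on array 4, so whether the pattern holds in both cultures is open, and IMD genes may share signal. IMD2, at -1.09 ± 0.04, was itself among the genes at least 2-fold negative on arrays 1 and 2. IMD3 and IMD4 may therefore not be independent of the genes that prompted the test, which was not repeated without them.

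Among the 1314 genes with a value on exactly 2 arrays, 28 were at least 2-fold positive and 16 at least 2-fold negative on both, against 1 with opposite signs (AIM17, 1.72 on array 1 and -1.05 on array 2). Of the 28, 8 are open reading frames of Ty retrotransposons, with means from 1.17 to 2.99, and 6 of these are among the 7 largest. They include YBL100W-A at 2.99 ± 0.16, YBL005W-A at 2.80 ± 0.16 and YAR010C at 2.45 ± 0.22. Ty copies are near-identical, so the 8 are not separate measurements. The fatty acid desaturase gene OLE1 averaged -1.92 ± 0.47 and the peptide transporter gene PTR2 -1.36 ± 0.16. GAT1, a factor of nitrogen-regulated transcription, averaged 2.35 ± 0.44 and SIR4, a silencing factor, 2.81 ± 0.08. These genes were chosen after their values were seen.

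The cell wall integrity response genes lay on the positive side of every array. Array centring alone is argued against: the list's median exceeded the array's median by at least 0.85 on each array. Dye bias in values that had not been turned stays open. Of random lists, 1e-04 reached the same lowest median over the arrays, the smallest share that 10000 lists can give, but this repeats the list's position on each array and the random lists were not matched on signal. That positive values mean a higher level with caspofungin is a hypothesis. The list holds genes known to be induced by wall stress, and 14 of the 14 members measured on at least 2 arrays had a positive mean, but this restates the pattern. The direction stays open and was not used in the results.

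Array 1 had the opposite sign to both other arrays at 164 genes after centring, against 103 for array 4 and 56 for array 2 (exact binomial p = 1.75e-13 for array 1 against array 2, treating genes as independent, which they are not). Examples chosen after their values were seen were FUN30 (1.56, -5.90 and -2.25 on arrays 1, 2 and 4), SCO1 (1.05, -4.07 and -2.56) and BCS1 (0.41, -3.87 and -2.50). A dye effect of the swapped hybridisation may account for this, because only array 1 had the treated RNA in Cy3, but the count of 164 is the pattern itself and the explanation stays open. No biological explanation was tested.

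Array 4 hardly correlated with array 1. Noise of array 4 alone is argued against, because noise would lower its correlation with array 2 too, which was 0.029 above that of arrays 1 and 2. Arrays 2 and 4 also share their dye orientation, which may have raised their correlation and weakens this argument. That arrays 1 and 2 are the dye swap of one culture may account for it, but stays open. Alone it would also lower the correlation of arrays 2 and 4, which was not seen, though their shared dye orientation may again have raised it. That array 4 opposed the others at 103 genes and array 2 at 56 restates the low correlation. IDP2, at 3.62 and 3.97 on arrays 1 and 2 and -0.14 on array 4, and YLR162W, at 3.80, 4.70 and -0.10, are examples chosen after their values were seen.

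Turning the sign of 1 array makes 4 splits of the 3 arrays into directions. The deposited one gave 7 genes at 2-fold on every array against at most 2 in the others, and 3 lists past the threshold against at most 0. So 1 of 4 splits was as large in both cases, and 4 splits are too few for a share under 0.05. For a list on one side of every array, turning 1 array makes values cancel, so the loss of its call was largely fixed in advance.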
